A study of Bos taurus with 8 samples.

How the data were processed

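Gene expression was measured in liver of Holstein bull cattle with 1-colour Agilent microarrays, on which Cy3-labelled RNA is hybridised to 60-base probes. The trial challenged cattle with a high-grain diet to bring on subacute ruminal acidosis (SARA), a drop in rumen pH during which bacterial lipopolysaccharide (LPS) is released. An egg-yolk antibody against LPS was given into the rumen through a fistula once a day for 14 days, and the trial followed a Latin square in which each animal received 0, 2 and 4 g in turn. The samples used here were taken 2 days after the challenge from 4 animals (numbers 19, 20, 23 and 24), each with 1 array at 0 g and 1 at 4 g per head per day, which makes 8 arrays and 4 per group. The 2 g group and the other cattle of the trial were not analysed here. The labels name liver as the tissue, while the extraction protocol in the same labels names rumen epithelium, and the period in which an animal received each dose is not in the labels, so period could not be a covariate.

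Per the file headers, the spot intensity values were produced by Agilent Feature Extraction 11.0.1.1 as processed signals, that is background-subtracted and spatially detrended brightness on a linear scale with no scaling between arrays; the submitters' processing notes name Feature Extraction 9.5 instead. Each file also holds the mean spot intensity and the median local background, which the authors deposited beside the processed signal, together with flags for spots well above background, saturated spots and outlier spots. The deposited series table holds the authors' own processed values on a log2 scale: each of its columns correlated with the log2 processed signal of its array at 1.00 across 15008 probes. Its columns were centred on the 75th percentile, with medians between −3.08 and −2.86, and no step beyond this centring was seen in the values. Probe coordinates in the files refer to the cattle assembly UMD 3.1, and they are given for the probes alone, since exons and untranslated regions are not part of the files and transcript lengths were not used.

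Each array had 15646 features, of which 536 control features were left out. The remaining 15110 features held 15008 distinct probes, 24 of them with several spots. All 8 arrays came from 1 slide and 1 scan, so neither could be tested as a batch, and the slide row (row 1 for animals 19 and 20, row 2 for animals 23 and 24) was tested in its place. Signal over background sets the depth of an array: 64.4% to 80.4% of the probes were well above background, the 75th percentile of the processed signal ran from 125.8 to 311.7, and no spot was saturated. The number of arrays limits the precision.

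For the comparisons, log2 of the processed signal was taken and each array's 75th percentile was subtracted. The 48 spots marked as outliers were left out, and spots of 1 probe were averaged on the log2 scale. Probes well above background on at least 4 of the 8 arrays were tested, which left 10985. Gene names came from the transcript accession of the probe where a RefSeq gene table of the assembly ARS-UCD2.0 held it (11273 probes), from a current symbol (3085) or from a synonym (36). The file's own name was kept for 293 probes, and 321 probes, 155 of them tested, had no gene symbol and were counted without being named. That assembly was used for names alone and none of its coordinates is given.

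The difference between 4 g and 0 g was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, with data.table version 1.17.8 for reading), with the animal as a block and Benjamini-Hochberg adjustment over the tested probes at 0.05. The block follows the design text, in which each animal is its own control, and the animal numbers in the titles. Deviations from the group means correlated between the 2 arrays of an animal at −0.19 to 0.21, so the pairing rests on the labels and not on this check. Confidence intervals are 95% intervals of the within-animal difference, whereas the SD beside a mean is the spread between 4 animals. Differences between animals were tested with the F-test on the animal terms of the same limma fit.

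Before the data were examined, 31 gene lists of pathways and cell types were written, and each was tested with camera in limma (preset correlation of 0.01, 1 probe per gene, the brightest, lists with at least 5 tested members, Benjamini-Hochberg adjustment over the lists). The named genes were also fixed by rule at that point: per direction 10 genes, filled up by the smallest unadjusted p among genes with an absolute log2 fold change of at least 0.58 and the same sign in all 4 animals where fewer passed, up to 3 members per list by the smallest unadjusted p, a set of liver, acute phase and LPS genes whatever their value, and the 10 genes with the smallest p between animals. A few of the genes so chosen are not reported here and were left out of the screen for single animals that stood apart. Another 5 lists (pancreatic acinar cells, pancreatic islets, adipocytes, smooth muscle and squamous epithelium) were written after the data had been seen.

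The fit was tested on simulated data with the variances that eBayes gave for the real arrays, 10964 probes and 200 changed probes in each of 10 draws. It recovered 7.0% of the probes changed 2-fold and 85.5% of those changed 4-fold, with 7.4 false calls per draw, and lists shifted by 0.3 on the log2 scale were called in 17 of 20 cases against 0 of 290 unshifted lists. The noise was drawn independently for each gene and array, while estimated correlations within the real lists reached 0.39. The 0 of 290 is thus no rate of false list calls for the real arrays. Some real arrays also shared their deviations from the group means (r = 0.62 and 0.55), so the recovered shares need not hold for them either. The alternatives fixed before the data were examined were another background correction (normexp with an offset of 50), quantile normalization or a median shift, the deposited series table, no filter or a filter on all 8 arrays, outlier spots kept, an intensity trend with robust variances, array weights, each animal left out, no block, the slide row as a block, an estimated correlation or fry for the lists, and the mean of all probes of a gene. Alternatives added after seeing the data left out single arrays or pairs of animals or added the slide columns as a covariate. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.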

Results

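Liver RNA of 4 Holstein bull cattle was profiled at 2 doses of a ruminal antibody against LPS, 0 g and 4 g per head per day, 2 days after a SARA challenge. Each animal gave 1 array per dose, so that the 8 arrays form 4 pairs. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD with n = 4 animals per dose. The brightness of the arrays differed: the 4 g array of animal 19 and the 0 g array of animal 20 had 75th percentiles of 125.8 and 126.3, and the other arrays lay between 218.0 and 311.7. Between 64.4% (0 g, animal 20) and 80.4% (0 g, animal 23) of the probes were well above background.

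Markers of hepatocytes, the main cells of liver, were strong on every array. Of 26 hepatocyte markers on the array, 24 were well above background on each of the 8 arrays, and albumin (ALB), the main plasma protein made by liver, stood at 6.60 ± 0.39 at 0 g and 6.64 ± 0.45 at 4 g. The urea cycle enzyme CPS1 stood at 6.22 ± 0.49 and 6.27 ± 0.47. Of 29 rumen epithelium markers, mostly keratins and desmosome genes, between 9 and 17 were well above background, with mean levels between −5.86 and −4.32. Kupffer cell and macrophage markers were measured on all arrays (17 or 18 of 18), and lymphocyte, neutrophil and red blood cell markers were fainter, with list means below −3.

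Transcripts of other tissues appeared on single arrays. On the 0 g array of animal 23, all 19 genes of a pancreatic acinar list lay more than 2 log2 units above the highest of the other 7 arrays, among them the digestive enzymes CEL at 8.77, PLA2G1B at 8.55 and CPA1 at 7.77. The list averaged 6.64 on this array and between −5.11 and −3.38 on the others. Islet genes were also measured there, such as the hormone PPY at 5.63, and 670 probes were well above background on this array alone. On the 0 g array of animal 19, 7 of 18 squamous epithelium genes lay more than 2 log2 units above the other arrays, including the keratin KRT6B at 0.62 and the protease inhibitor A2ML1 at −0.59. Of the others, KRT5 was not highest there, and TP63 was well above background on 0 arrays. This array also had the most rumen epithelium markers well above background (17 of 29), 3 of them more than 2 log2 units above all other arrays. The acinar, islet and squamous epithelium lists were written after the values had been seen.

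**Figure D1:**
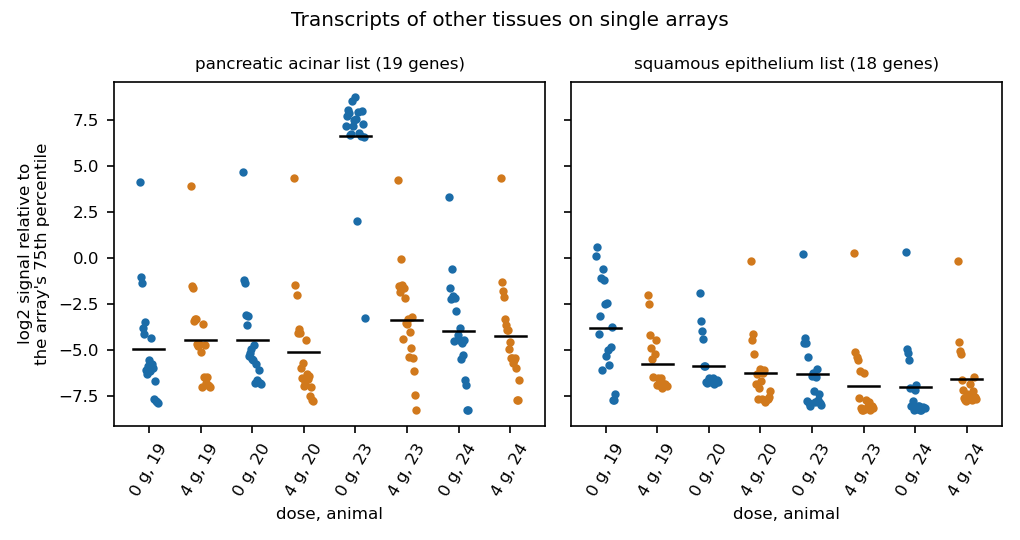
Log2 signal relative to the 75th percentile (vertical axis) of 19 pancreatic acinar genes and 18 squamous epithelium genes on each of the 8 arrays (horizontal axis, dose and animal), with 1 point per gene, blue for 0 g and orange for 4 g, and a black line at the list mean. The acinar list averages 6.64 on the 0 g array of animal 23 and at most −3.38 elsewhere.

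The first comparison asked which liver genes differed between 4 g and 0 g of antibody in the same animals. The widest gap with a narrow interval was in FABP4, a fatty acid carrier of adipocytes and macrophages, which stood at −0.09 ± 2.05 at 0 g and −2.53 ± 1.71 at 4 g. The log2 difference was −2.45 (95% CI −3.07 to −1.83) and negative in 4 of 4 animals. On the same side, the muscle actin ACTA1 differed by −1.65 (SE 0.28), the pericyte proteoglycan CSPG4 by −1.13 (SE 0.24) and desmin (DES), a filament of muscle and stellate cells, by −1.13 (SE 0.26), each lower in 4 of 4 animals. On the higher side, VNN1, a pantetheinase driven by the fatty acid receptor PPARA, differed by 1.08 (SE 0.33), and the hypoxia-responsive gene ANKRD37 by 0.90 (SE 0.24), both higher in 4 of 4 animals. VNN1 differed by 1.68 and 1.77 in animals 23 and 24, whose labels are questioned below, and by 0.43 and 0.46 in animals 19 and 20. None of these genes passed the test over all 10985 probes: the adjusted p of limma was 0.588 for FABP4 and 1.00 for the other genes named. The same sign in 4 of 4 animals was a condition for picking these genes, so it is no separate result.

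With limma, 0 of 10985 probes changed at an adjusted p under 0.05, and 121 probes had an unadjusted p under 0.05, of which 37 were higher and 84 lower at 4 g. Independent noise alone would give 549 such probes, so the p values are not well calibrated here. The shortfall does not show that genes were unchanged. The 2 arrays of every animal can be parted into 2 groups in 8 ways. With the block, 66 to 332 probes resulted where the dim 4 g array of animal 19 and 0 g array of animal 20 fell apart, as by dose. Where they fell together it was 580 to 1757. This contrast was drawn after the values had been seen. Among the 10 genes that led on the lower side were also MYOC (−2.38), a secreted glycoprotein, LOC786512 (−1.68), the matricellular protein CCN3 (−1.47), the cadherin CDH7 (−1.32), the membrane protein MAL (−1.14) and the protease inhibitor SERPINE2 (−1.04). On the higher side were LRRN4 (1.67), SEC16B (1.04), the carbonic anhydrase CA13 (0.87), LOC100126815 (0.85), the activin-type receptor ACVR1C (0.80), the costimulatory receptor TNFRSF9 (0.80), the calpain CAPN8 (0.73) and ANKRD1 (0.70). Several of these genes were well above background on part of the arrays only, so their differences are set against dim signals. At 0 g this was 1 of 4 arrays for LRRN4, 2 for CAPN8 and 3 for ANKRD37, TNFRSF9 and LOC786512. At 4 g it was 1 of 4 for LOC786512 and CDH7, 2 for MYOC and 3 for CSPG4, SERPINE2 and DES. All kept 1 sign in 4 of 4 animals, as the rule that picked them required. Over all tested probes, 558 did so (5.08%, against 12.5% by chance). The FABP4 probe lies on chromosome 14 at 46833756 to 46833815, that of VNN1 on chromosome 9 at 71833299 to 71833330 and that of DES on chromosome 2 at 108077315 to 108077493 (UMD 3.1). PCP4, a calmodulin-binding peptide, was well above background on 4 of 4 arrays at 0 g and 0 of 4 at 4 g, a bound of at least 1.56-fold lower at 4 g with an adjusted p of 1.00. The bound sets the mean at 0 g against the dimmest well-measured signal of each 4 g array.

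**Figure D2:**
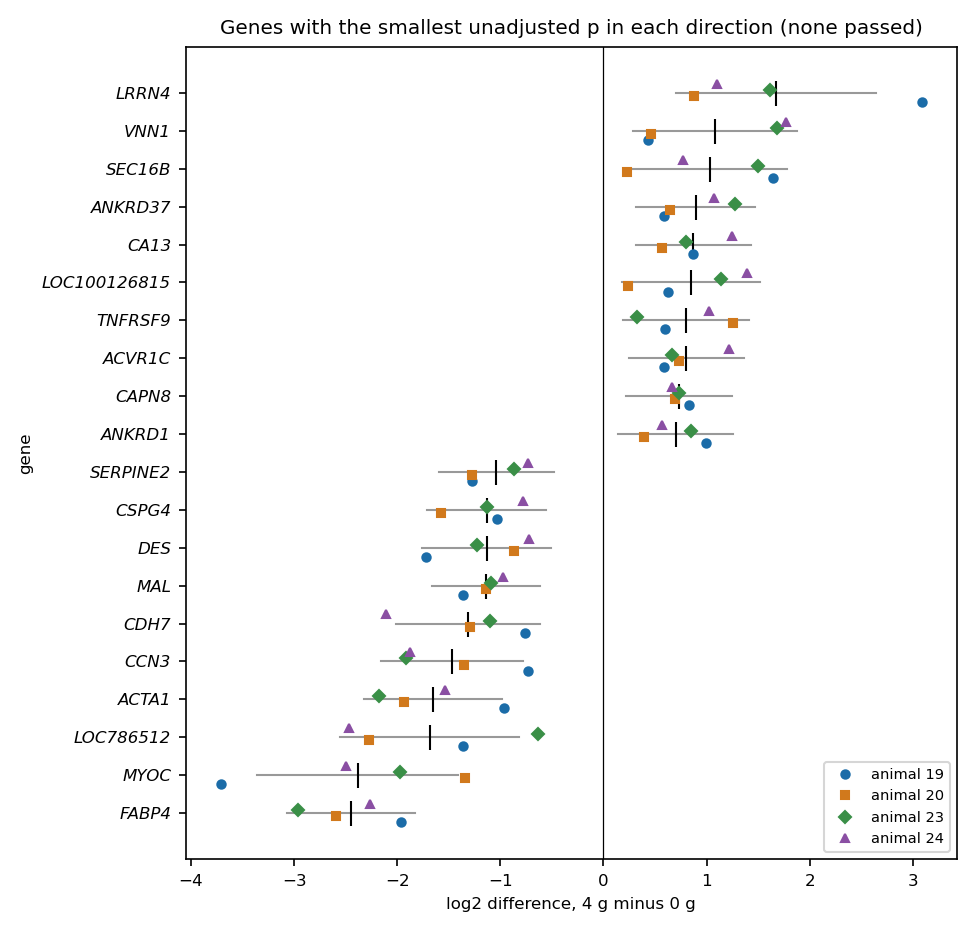
Log2 difference, 4 g minus 0 g (horizontal axis), of the 20 genes (vertical axis) that led in each direction, with coloured markers for the 4 animals, a black tick for the mean difference and a grey line for its 95% CI. FABP4 lies lowest at −2.45, and none of the genes passed the test.

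The median 95% interval reached 0.70 on the log2 scale (1.63-fold) to either side of the difference, and it excluded a 2-fold change for 64.3% of the probes. The share of higher probes at an unadjusted p under 0.05 was 37 of 121 here, 59 of 131 after quantile normalization and 7 of 17 with normexp background correction, each among the probes of its own fit. With normexp the log2 fold change of FABP4 was −1.18, and LRRN4, ANKRD37 and CAPN8 came out slightly below 0.

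Acute phase proteins, which liver makes during inflammation, were the readout closest to the trial's question of whether the antibody alters the response to LPS. Haptoglobin (HP) stood at 5.80 ± 0.50 at 0 g and 4.89 ± 1.55 at 4 g, a difference of −0.90 (SE 0.64) that was negative in 3 of 4 animals and 1.51 in animal 24. The LPS-binding protein LBP differed by −0.44 (SE 0.24) and was lower in 4 of 4 animals. Hepcidin (HAMP), the iron hormone induced by inflammation, differed by −0.94 (SE 0.35) and was lower in 3 of 4. The pentraxin APCS differed by −0.89 (SE 0.34) and was lower in 4 of 4, but mainly in animals 23 and 24, whose labels are questioned below. It stood at 6.78 at 0 g and 5.27 at 4 g in animal 23, and at 6.73 and 5.15 in animal 24. In animal 19 it stood at 6.48 and 6.46, and in animal 20 at 6.62 and 6.16. C-reactive protein (CRP) differed by −0.01 (SE 0.38). Of 26 measured members 19 were lower and 7 higher at 4 g, with a median of −0.08, and the list did not pass camera (adjusted p = 0.0636, and 0.947 with an estimated correlation). The probe for SAA3 was well above background on 0 arrays. The list median was negative in animals 19, 20 and 23 (−0.75, −0.18 and −0.18) and 0.39 in animal 24. Without animal 23 or animal 24 the list passed, with medians of −0.07 and −0.23 and camera adjusted p values of 0.0153 and 0.00140. Without animal 20 its median was −0.17 and it did not pass (camera adjusted p = 0.366). Without animal 19 its median was 0.08 (camera adjusted p = 0.878).

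**Figure D3:**
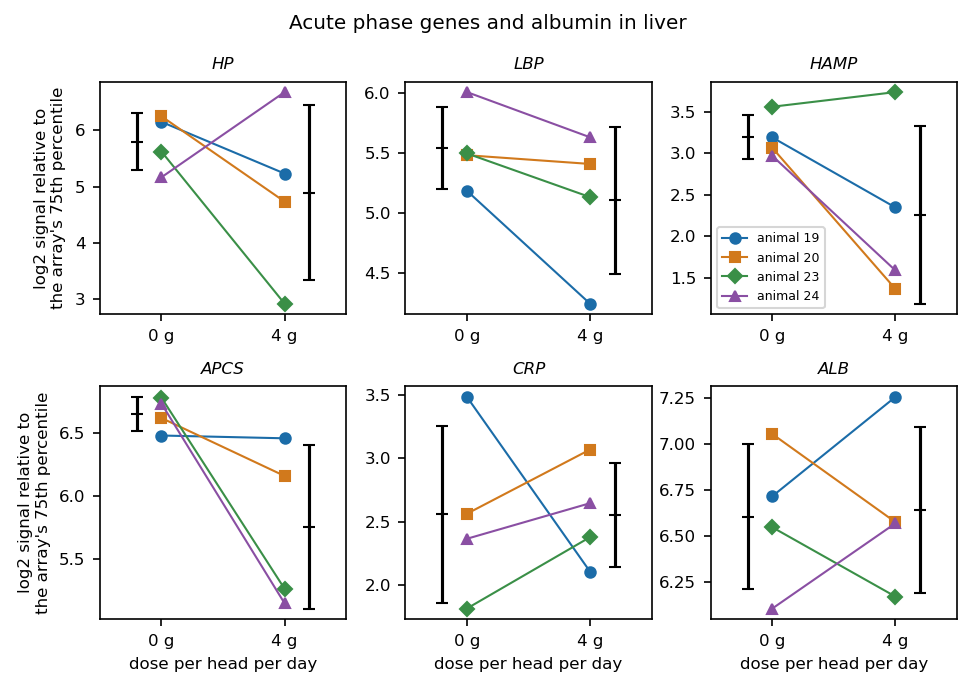
Log2 signal relative to the 75th percentile (vertical axes) of HP, LBP, HAMP, APCS, CRP and ALB at 0 g and 4 g per head per day (horizontal axis), with a line per animal and black bars for the mean ± SD of 4 animals. LBP and APCS are lower at 4 g in 4 of 4 animals, and none of these genes passed the test. APCS is nearly level in animal 19 (6.48 at 0 g and 6.46 at 4 g).

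None of the genes that sense LPS or answer to it passed. The receptor gene TLR4 differed by 0.27 (SE 0.42), its co-receptor CD14 by 0.09 (SE 0.24), and the NF-kB subunit RELB by 0.43 (SE 0.22), higher in 4 of 4 animals. Of 29 measured genes of LPS sensing and NF-kB, 19 were higher and 10 lower (median 0.08, camera adjusted p = 0.366), among them AOAH, an enzyme that inactivates LPS, at −0.48 (SE 0.27) and NFKBIZ at −0.26 (SE 0.23). The cytokines TNF (0.22, SE 0.37) and IL1B (−0.22, SE 0.35) and the neutrophil chemokines CXCL8 (0.34, SE 0.24), GRO1 (0.47, SE 0.24) and CXCL3 (−0.65, SE 0.43) did not pass, and the IL6 probe was well above background on 0 arrays. The 23 measured cytokines and chemokines had a median of 0.05 while their test pointed down (adjusted p = 0.883). The signs of TLR4, TNF and CRP and of the medians of both lists turned with normexp background correction.

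Of the 31 gene lists, 4 passed camera with its preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.284) or with fry. The estimates were 0.016 for the stellate and fibroblast, 0.088 for the endothelial, 0.021 for the interferon and 0.021 for the immediate early list. Apart from the endothelial list these lie near the preset 0.01, so the lost calls there are no sign of strong correlation. The estimates rest on the 3 residual degrees of freedom of the fit. Camera with an estimated correlation also takes its p from these 3 degrees of freedom, which the preset version does not. A call lost with an estimated correlation thus need not come from correlation between the genes. Adjusted over the list alone, 0 lists held a member that passed, as over all probes. The clearest was the list of stellate cell and fibroblast genes, which make and contract the connective tissue of liver: 20 of 23 measured members were lower at 4 g (median −0.28, camera adjusted p = 7.54e-09, but adjusted p = 0.284 with an estimated correlation). Its members included DES, the actin-binding protein TAGLN (−1.04, SE 0.26) and the collagen COL1A2 (−0.95, SE 0.27), each lower in 4 of 4 animals. DES and TAGLN are also in a smooth muscle list given below, so their values do not part these cell types. The median of the stellate and fibroblast list was negative in all animals, at −0.12, −0.51, −0.38 and −0.26 for animals 19, 20, 23 and 24. Without the 0 g array of animal 23, which carried the pancreatic transcripts, and with no block the median was −0.27 and the preset adjusted p 5.82e-09. It was −0.31, −0.18, −0.19 and −0.28 without animal 19, 20, 23 and 24 in turn (largest adjusted p = 0.00371) and −0.12 with normexp background correction. With no block and without the 2 dimmest arrays it was −0.16 (camera adjusted p = 0.0139).

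Endothelial genes were lower in 18 of 21 cases at 4 g (median −0.20, camera adjusted p = 0.00144, and adjusted p = 0.636 with an estimated correlation). The sialomucin EMCN differed by −0.56 (SE 0.25), the adhesion molecule PECAM1 by −0.50 (SE 0.32) and the clotting protein VWF by −0.34 (SE 0.23). The animals differed, with list medians of −0.60 and −0.28 in animals 19 and 23 and 0.13 and 0.09 in animals 20 and 24, and without animal 19 the list did not pass (adjusted p = 0.403). Nor did it with normexp background correction (median −0.12, adjusted p = 0.0577) or, with no block, without the 2 dimmest arrays (median −0.06, adjusted p = 0.280). Its median was −0.40 without animal 20 and −0.12 without animal 23.

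Interferon-stimulated genes, part of the antiviral response, were higher at 4 g in 25 of 35 cases (median 0.21, camera adjusted p = 0.00329, and adjusted p = 0.520 with an estimated correlation). The antiviral enzyme gene OAS1Z differed by 1.52 (SE 0.73), IFI35 by 0.63 (SE 0.34) and HERC6 by 0.61 (SE 0.33), each higher in 3 of 4 animals, and the list medians were 0.01, 0.19, 0.33 and 0.30 in animals 19, 20, 23 and 24. OAS1Z differed by 3.39 and 3.13 in animals 23 and 24 and by −0.68 and 0.23 in animals 19 and 20. The list median was 0.05 with normexp background correction and 0.07 in animals 19 and 20 alone, where the list did not pass (adjusted p = 0.420). Immediate early genes, which respond within minutes to stress and growth signals, were lower in 17 of 24 cases (median −0.17, camera adjusted p = 0.00329, and adjusted p = 0.520 with an estimated correlation). Among them SOCS3, a feedback inhibitor of cytokine signals, differed by −1.04 (SE 0.53), the growth arrest gene GADD45G by −0.58 (SE 0.27) and FOSL2 by −0.57 (SE 0.28). The list medians were −0.21, −0.07, −0.38 and 0.14 in animals 19, 20, 23 and 24, and the median was −0.05 without animal 23 and −0.29 without animal 24. Without animal 20 neither list passed, with adjusted p values of 0.151 for the interferon genes and 0.130 for the immediate early genes. The immediate early list was no longer past the threshold without the 0 g array of animal 23 either (median −0.10, adjusted p = 0.0983, no block). With no block and without the 2 dimmest arrays its median was 0.035 and it did not pass (camera adjusted p = 0.836).

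**Figure D4:**
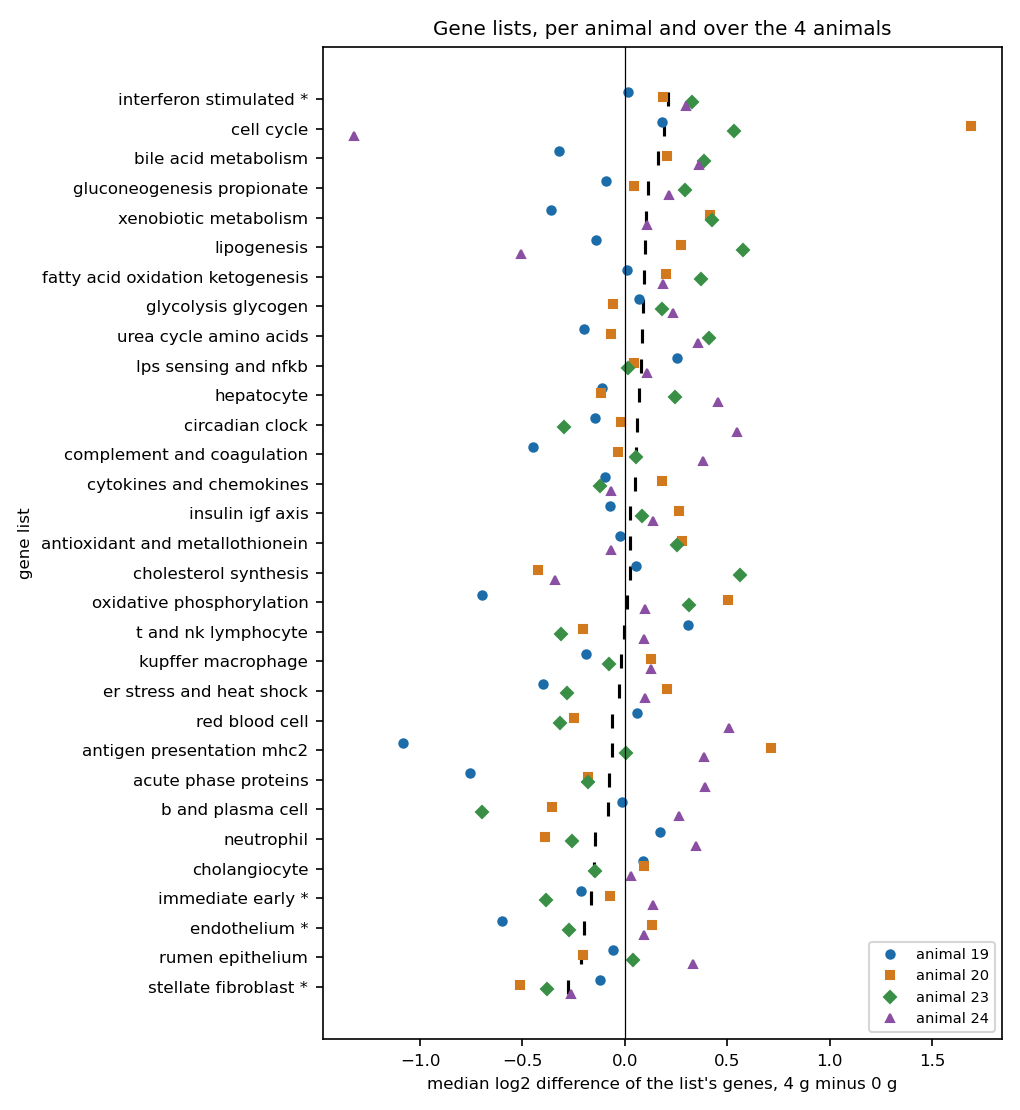
Median log2 difference, 4 g minus 0 g (horizontal axis), of each of the 31 gene lists (vertical axis), with coloured markers for the 4 animals, a black tick for the list median of the fitted differences and an asterisk for lists past camera with the preset correlation. The stellate and fibroblast list is lowest at −0.28, and 0 lists passed with an estimated correlation.

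Lists of liver metabolism did not pass with the settings used for the values given here, and some did in alternatives fixed in advance. The fatty acid oxidation, bile acid and xenobiotic lists passed as higher at 4 g with normexp background correction, with the filter on all 8 arrays, with array weights and without animal 19. The urea cycle list passed in these fits except that with the filter, and fatty acid oxidation also with an intensity trend and robust variances. With an estimated correlation the adjusted p was 0.947 for each of these lists. Fatty acid oxidation and ketogenesis came closest, with 20 of 31 genes higher (median 0.09, camera adjusted p = 0.0756), among them VNN1, the peroxisomal enzyme EHHADH (0.64, SE 0.30) and the thiolase ACAA2 (0.48, SE 0.23). Of the bile acid genes 14 of 22 were higher (median 0.16, adjusted p = 0.0966), with the exporter SLC51B at 0.84 (SE 0.53), the transporters SLC27A2 at 0.39 and ABCB11 at 0.40, and CYP7A1, the rate-limiting enzyme of bile acid synthesis, at −0.34 (SE 0.81). SLC51B stood at 1.00 at 0 g and 3.21 at 4 g in animal 23, and at 1.68 and 3.56 in animal 24. It was lower at 4 g in animals 19 and 20. Xenobiotic metabolism had 26 of 36 genes higher (median 0.10, adjusted p = 0.210), although its member CYP2B6 differed by −1.69 (SE 0.80) and was lower in 3 of 4 animals, against 0.69 (SE 0.41) for CYP1A1 and 0.46 (SE 0.26) for FMO5. In the urea cycle and amino acid list (median 0.08, adjusted p = 0.508) the glutamine synthetase gene GLUL differed by −0.67 (SE 0.24) and was lower in 4 of 4 animals, while OTC (0.64, SE 0.27) and HAL (0.55, SE 0.29) were higher in 4 of 4.

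Gluconeogenesis and propionate use had a median of 0.11 (adjusted p = 0.710), with PCK1, which controls glucose output, at −0.44 (SE 0.36), GOT1 at 0.44 and ACSS1 at −0.27. Glycolysis and glycogen had a median of 0.09 (adjusted p = 0.508), with UGP2 at −0.47, TPI1 at 0.37 and PFKFB1 at 0.43. Lipogenesis (median 0.10, adjusted p = 0.894) and cholesterol synthesis (median 0.02, adjusted p = 0.715) had medians above 0 while their tests pointed down, and their members PLIN5 (−0.79), MID1IP1 (−0.81), DGAT2 (−0.57), NPC1L1 (−0.57) and INSIG1 (−0.35) lay below 0. Oxidative phosphorylation had a median of 0.01 (adjusted p = 0.940), with UQCRB at −0.56, CYCS at −0.25 and NDUFS3 at 0.30. The insulin and IGF list had a median of 0.03 (adjusted p = 0.715), with LEPR at 0.66, HGF at 0.42 and IGF1 at 0.34.

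Among stress and regulatory lists, antioxidant and metallothionein genes had a median of 0.03 (adjusted p = 0.551), with the metal-binding MT1A at −0.86 (SE 0.28), lower in 4 of 4 animals, the glutathione synthesis gene GCLC at 0.60 (SE 0.24), higher in 4 of 4, and SLC39A8 at 0.40. The ER stress and heat shock list had a median of −0.03 (adjusted p = 0.366), with ASNS at −1.03 (SE 0.74), ATF3 at −0.34 and TRIB3 at −0.29. The circadian list had a median of 0.06 (adjusted p = 0.883), with NFIL3 at −0.62 (SE 0.22) and lower in 4 of 4 animals, PER3 at 0.75 and NR1D2 at 0.58. Cell cycle genes were higher in 18 of 25 cases (median 0.19, adjusted p = 0.110), with BUB1 at 0.74, PLK1 at 0.44 and MCM3 at 0.40. Their medians per animal were the widest of all lists, at 1.69 in animal 20 and −1.32 in animal 24. Complement and coagulation had a median of 0.05 (adjusted p = 0.508), with F11 at 0.69, F7 at 0.32 and F13B at 0.29. It passed as higher with normexp, with array weights and without animal 19, but not with an estimated correlation (adjusted p = 0.947). MHC class II genes had a median of −0.07 with a test that pointed up (adjusted p = 0.998), with BOLA-DRB3 at 0.29, BOLA-DOB at 0.26 and CD83 at 0.15.

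The other cell type lists did not pass with these settings either. Hepatocyte markers had a median of 0.07 (adjusted p = 0.653), with 19 of 24 higher and 5 lower, among the higher APOB at 0.46 and TAT at 0.37. They passed as higher with normexp and without animal 19, but had an adjusted p = 0.978 with an estimated correlation. Kupffer cell and macrophage markers had a median of −0.02 (adjusted p = 0.894), with TIMD4 at 0.36, LYZ at 0.29 and MARCO at −0.22. Medians were −0.08 for B and plasma cells (adjusted p = 0.201), with DERL3 at −0.59, MS4A1 at −0.36 and MZB1 at −0.22. This list passed as lower with array weights and without animal 24, but had an adjusted p = 0.947 with an estimated correlation. The median was 0.00 for T and NK lymphocytes (adjusted p = 0.715), with CD28 at 0.79, CD3D at −0.60 and PRF1 at −0.36. Neutrophil markers had a median of −0.15 (adjusted p = 0.368), with S100A12 at −0.43 and lower in 4 of 4 animals, CXCR1 at 0.52 and CSF3R at 0.30. Bile duct markers had a median of −0.15 (adjusted p = 0.715), with osteopontin (SPP1) at 1.33 (SE 0.46), higher in 4 of 4 animals, EPCAM at −1.09 (SE 0.53) and ANXA4 at 0.52. SPP1 stood at −4.53 at 0 g and −1.92 at 4 g in animal 23, and at −3.84 and −1.76 in animal 24. In animal 19 it stood at −3.81 and −3.20, and in animal 20 at −2.92 and −2.88. Of the bile duct markers 3 lay more than 2 log2 units above all other arrays on the 0 g array of animal 23, where the pancreatic transcripts were. Rumen epithelium markers had a median of −0.21 (adjusted p = 0.861), with SBSN at 0.93, GJB2 at −0.81 and IVL at −0.78. Red blood cell markers had a median of −0.06 (adjusted p = 0.715), with HBQ1 at −0.54 and HBE1 at −0.31.

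Other lists passed in single alternatives fixed in advance. Gluconeogenesis did as higher at 4 g with normexp, oxidative phosphorylation and MHC class II as higher without animal 19, and cell cycle genes as higher without animal 24. Lipogenesis and cholesterol synthesis passed as lower without animal 23, and acute phase proteins as lower with the filter on all 8 arrays and with an intensity trend and robust variances. Their adjusted p values with an estimated correlation were 0.947 to 0.999.

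Some list members were well above background on part of the arrays only. At 4 g this was 1 of 4 arrays for SOCS3, UQCRB and HBQ1, and at 0 g 2 of 4 for OAS1Z, LEPR and CD28. It was 3 of 4 at both doses for TLR4, TNF, NPC1L1, CD3D, MS4A1, CXCR1 and GJB2. It was 3 of 4 at 4 g for OAS1Z, LEPR, CYP7A1, MID1IP1, CYP2B6 and IVL, and 3 of 4 at 0 g for PER3, BUB1, SBSN and HBQ1.

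The second comparison asked which genes differed between the 4 animals whatever the dose. The meiotic cohesin gene REC8 stood at 2.80 on both arrays of animal 20 and between −3.58 and −2.22 on the other arrays. OOSP2, an oocyte-secreted protein, stood at −6.52 and −6.86 in animal 19 and between −2.86 and −1.53 elsewhere, with a signal not well above background on either array of animal 19. The liver pyruvate kinase gene PKLR averaged −3.03 in animal 20 and between −0.13 and 0.45 in the others, and DPP4, a peptidase that inactivates incretins, −1.45 in animal 20 against 0.44 to 0.86. With the F-test of limma, 0 of 10985 probes passed (adjusted p = 0.103 for REC8 and OOSP2), and 301 had an unadjusted p under 0.05. Among the genes that followed were FABP4 (adjusted p = 0.252), GATA3 (0.912), WFDC2 (0.957), CDH7 and FBLN2 (0.969). GATA3 was not well above background on any array of animals 23 and 24, nor CDH7 at 4 g in animals 19, 23 and 24.

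Some genes had 2 separate levels across the arrays, with a gap of more than 2 log2 units between them, and are named here after their values had been seen. The immune GTPase gene GIMAP4 (chromosome 4, 113866890 to 113866949) stood between 3.28 and 4.32 on both arrays of animal 19 and on the 0 g arrays of animals 23 and 24, and between −0.25 and 0.23 on both arrays of animal 20 and the 4 g arrays of animals 23 and 24. LOC768255 and GIMAP6 on the same chromosome and the cytokine receptor gene IL20RA on chromosome 9 had the same division, and the NK ligand gene ULBP3 on chromosome 17 the opposite one. Of 67 such probes, 40 parted the 2 dimmest arrays from the rest and were left out. Of the remaining 27, 11 on 7 chromosomes parted the 0 g arrays of animals 23 and 24 from their 4 g arrays, and 0 parted these animals from each other. None parted all 4 animals by dose. In animals 19 and 20, 13 parted the animals and 0 the doses. Without the 4 g array of animal 23 and the 0 g array of animal 24, and with no block, 0 probes and 5 lists passed.

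**Figure D5:**
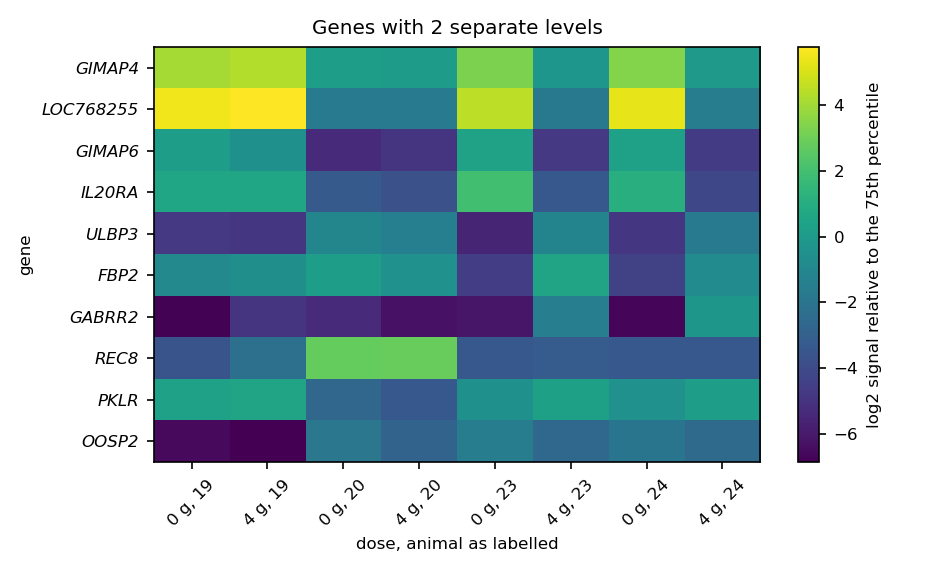
Log2 signal relative to the 75th percentile (colour scale) of 10 genes with separate levels (vertical axis) on the 8 arrays (horizontal axis, dose and animal as labelled). GIMAP4, LOC768255, GIMAP6 and IL20RA are high on both arrays of animal 19 and on the 0 g arrays of animals 23 and 24.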

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

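The tests of explanations in this part were chosen only after the result each concerns had been seen.

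RNA of pancreatic cells in the sample is a candidate explanation of the acinar enzyme transcripts on the 0 g array of animal 23. The 19 of 19 genes more than 2 log2 units above the other 7 arrays come from a list written after these values had been seen, so they restate the pattern and do not test it. A brighter array or its scaling is excluded: 1.38% of the probes well above background on this array lay that far above the others. Lower acinar levels on the other 3 arrays of the same slide row may come from carry-over between neighbouring arrays, as 10 genes had a median there above all arrays of the other row. They may also come from pancreatic cells in the other sample of animal 23, but 9 genes on the 0 g array of animal 24 also lay above all arrays of the other row, so the tests cannot part these explanations.

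The 4 g array of animal 19 and the 0 g array of animal 20, the dimmest arrays, have neither dose nor animal in common but shared their deviations from the group means (r = 0.62), with RPSA (−2.96), FCGRT (−2.93) and INHBE (−2.90) low and THRAP3 (2.60) high on both. Position in the middle columns of the slide is a candidate explanation, as in the other slide row, the only test, the middle pair also had the highest correlation of 6 pairs (r = 0.548, the next 0.213). The arrays of that pair were the brightest (75th percentiles of 311.7 and 310.7), so the test cannot part position from matched brightness. Nor is the test independent, as the group means hold arrays of both rows. A steady rise or fall of these deviations with the GC content of the probes is excluded (Spearman rho 0.00906). Other forms of a GC effect were not tested. Whether the slide itself or an earlier step tied to this position is the cause was not tested.

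The probes with 2 separate levels raise the question whether labels were exchanged between arrays of animals 23 and 24. Among 27 probes, 18 kept a pairing that joins the 0 g arrays of both animals and their 4 g arrays, the most of all possible pairings of the 8 arrays (the next had 13), and 7 kept the labelled pairing. These 7 are among the 18, with all arrays of animals 23 and 24 on 1 side, so they favour neither pairing. The others were the 11 that parted the doses of these animals, against 0 that parted the animals. Exchanged labels are a possible explanation, since among 78 probes with a smaller gap of 1 to 2 log2 units 21 kept that pairing and 15 the labelled one, though 23 kept a pairing by the middle columns. Most probes with this smaller gap, 449 of 527, parted the 2 dimmest arrays and were left out. A response to the dose shared by all animals is excluded, as 0 probes parted all 4 animals by dose. The deviations of the middle columns parted 1 of the 27 probes but had the most of the smaller-gap probes, so they stay open, as does a response in animals 23 and 24 alone, and the labels were kept as given.

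Single animals stood apart from the other 3 of their dose group in 20 of 326 groups tested with Dixon's Q. Chance alone would flag 1 in 20 groups, which is 16.3 of the 326, so the count lies near chance. Some of the genes had been picked for differences between animals, and the acinar list for its levels on 1 array. Such picks raise the count, so it is no sign of more cases than chance gives. A case listed here may thus be chance. For genes in the 0 g group, Q was 0.878 for SEC16B (animal 24), 0.913 for LOC786512 and 0.862 for MARCO (animal 19), and 0.910 for OOSP2 (animal 19). In animal 20 it was 0.914 for CXCL3, 0.894 for BOLA-DOB, 0.856 for CYP2B6, 0.860 for DPP4 and 0.970 for REC8. CXCL3 stood at 4.69 there, against 3.25 to 3.38 in the other animals. In the 4 g group, Q was 0.876 for PCK1, 0.901 for MID1IP1 and 0.919 for OOSP2 (animal 19), and 0.905 for GRO1 and 0.924 for PKLR (animal 20). PCK1 stood at −3.74 in animal 19, against −1.04 to −0.65.

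For list means, Q was 0.855 for MHC class II, 0.891 for bile acid metabolism and 0.847 for antioxidant and metallothionein genes, each for the 4 g array of animal 19. It was 0.938 for the insulin and IGF list on the 4 g array of animal 20, and 0.916 for the pancreatic acinar list on the 0 g array of animal 23. The mean correlation with the other arrays was 0.942 for the 4 g array of animal 19, against 0.968 to 0.971 in its group (Q = 0.889). This array held 7 of the 20 cases, and it is 1 of the 2 dimmest.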

How the results depend on the processing

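The 7 alternatives that leave out single arrays or pairs of animals or add slide columns were chosen only after the result had been seen, and the other 18 before.

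The count of 0 probes changed between 4 g and 0 g held in all fits but 1: with no block and without the 2 dimmest arrays 5 probes passed, GIMAP4, GIMAP6, LOC768255, IL20RA and ULBP3, all with 2 separate levels. A threshold of an unadjusted p under 0.05 with an absolute log2 fold change of at least 1 gives 47. With no block, so without the pairing by animal, 0 probes and 4 lists passed. Between animals 0–1 probes passed when an animal was left out.

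The 4 passing lists were 10 with normexp background correction, 8 with the filter on all 8 arrays, 10 with array weights, 0 with an estimated correlation and 0 with fry. Leaving out an animal gave 2–11 lists, no block without the 2 dimmest arrays 7, and animals 23 and 24 alone 13. The stellate and fibroblast list passed in 23 of 25 alternatives, the interferon list in 21, the endothelial and immediate early lists in 20 and the acute phase list in 7. List medians turned sign in several fits. Among them were the acute phase list (0.08 without animal 19, 0.13 with animals 23 and 24 alone), MHC class II (0.33 without animal 19) and cholesterol synthesis (−0.21 without animal 23). Others were immediate early genes at 0.035 with no block and without the 2 dimmest arrays, oxidative phosphorylation at −0.19 with animals 19 and 20 alone, and cell cycle genes at −0.43 with animals 23 and 24 alone. The latter 2 lists passed in opposite directions in the fits of 2 animals. Oxidative phosphorylation passed as lower with animals 19 and 20 and as higher with animals 23 and 24, and cell cycle genes the other way round. The animals of a pair could differ, so these are no directions of single animals. The oxidative phosphorylation median was −0.70 in animal 19 and 0.50 in animal 20. That of cell cycle genes was 0.53 in animal 23 and −1.32 in animal 24.

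The 121 probes at an unadjusted p under 0.05 became 17 with normexp, 191 with no filter, 406 with array weights, 406, 342 and 58 without animal 19, 20 and 23. Where the block was dropped as well, they became 309 without the 2 dimmest arrays and 50 without the 0 g array of animal 23. They became 16 with animals 19 and 20 alone, 454 with animals 23 and 24 alone and 434 with the middle columns by row. Between animals, 301 became 42 with normexp, 474 with no filter, 182 with array weights and 595 with the middle columns by row.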

Other observations

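In a smooth muscle list written after the values had been seen, 12 of 16 measured genes were lower at 4 g (median −0.39, camera adjusted p = 3.65e-11, but adjusted p = 0.0650 with an estimated correlation). The other 4, CALD1, MYLK, TPM1 and MYH11, were higher. The list shares 4 genes with the lists fixed earlier, and DES, TAGLN and ACTA1 led to its choice, so its p is no independent test. Neither is that of an adipocyte list, written after FABP4 had been seen to lead and sharing 2 genes with the earlier lists. Adipocyte genes were lower in 5 of 8 cases (median −0.37, adjusted p = 0.000350, and adjusted p = 0.0650 with an estimated correlation of −0.049), with FABP4 among them. Of 14 adipocyte genes on the array, 3 lay more than 2 log2 units above all other arrays on the 0 g array of animal 23, which carried the pancreatic transcripts.

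All 12 measured acinar genes were lower at 4 g (median −2.59, camera adjusted p = 1.97e-10, and adjusted p = 0.186 with an estimated correlation), as were 4 of 5 islet genes (median −0.82, adjusted p = 0.0104, and adjusted p = 0.199 with an estimated correlation). The acinar differences rest mainly on the 0 g array of animal 23 and are not read as a response to the dose. Of the 5 measured islet genes, NEUROD1 and PCSK2 were not highest on that array.

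The splits of the samples were fixed before the data were examined, and the other tests named in this part were chosen only after the result had been seen. With 0 probes found between doses, all 35 of 35 splits of the 8 arrays into equal groups give at least as many (highest 6), which holds whatever the data and tests nothing. For probes at an unadjusted p under 0.05, 31 of 35 give at least as many as the doses did with no block, so chance cannot be excluded. The highest of these, 1960, parts the slide rows. Of the 8 splits that part every animal, 6 give at least the 4 lists found with the block (highest 12), and 8 splits are too few for a share under 0.05. With no block 25 of 35 splits give at least 4 lists (highest 12), so chance cannot be excluded.

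The arrays in the middle columns of each slide row resembled each other across animal and dose (r = 0.62 and 0.55), and the slide row was tied to the animals. Arrays placed at random over several slides would part these effects, and genotypes of the animals would trace each array to its animal.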
